A study of Mus musculus with 6 samples.

How the data were processed

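Total RNA of 6 samples of BCR-ABL1-transformed mouse B cell precursors, 3 wild type and 3 knockout for Etv5, was labelled with biotin and hybridised to 1-colour Affymetrix arrays, per the labels' protocols. The deposited table holds log2 values of 35556 probe sets, 1 column per sample; RMA (robust multi-array average) and Partek 6.5 are named in the submitters' processing notes. RMA corrects the background, quantile-normalizes probe intensities and summarises them per probe set, which compresses differences of dim probe sets. The log2 scale was read from the values, which run from 2.58 to 14.7. Background settings, the chip definition, any filter, detection calls and the authors' test are not given in the sources used here. No column was left unused. The number of arrays limits the precision; the table gives no detection p-values, so no probe set could be called absent.

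Genotypes and sample numbers were taken from the sample titles. Probe sets were named through a platform annotation table: 21789 had exactly 1 gene symbol, 1621 had several and 12146 had none listed there. Of the single-gene probe sets, 21698 matched the gene table of assembly GRCm38.p6 by gene identifier, and 0 symbols changed. Positions are not printed because the build behind the array design is not given; the gene table was used for names, for chromosome membership and for the order of neighbouring genes. A gene with several probe sets was represented by the one with the highest mean over all 6 arrays, giving 19938 genes, of which 999 had several probe sets; in 0 genes did probe sets pass in opposite directions. Control probe sets are not marked in the tables used and stayed in the test. Some genes fixed in the lists have no single-gene probe set in the annotation used here, so 551 of 615 list entries were measured.

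The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, no covariate, all 6 samples, no filter on dim probe sets). Benjamini-Hochberg adjustment ran over all 35556 probe sets with a threshold of 0.05, and the prior added 2.23 degrees of freedom for a total of 6.23. Changes are knockout minus wild type in log2 units with the moderated standard error. An exact permutation test of 3 samples against 3 cannot go below p = 0.10, so single genes were not tested that way. The lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those named as chosen later. Of 24 lists, 22 were tested with camera (two-sided, correlation between genes preset at 0.01, against all other genes, adjusted over the 22 lists) and 2 (sex-linked genes and histones) served as checks. Camera was repeated with the correlation estimated for each list, and fry was run as a further test.

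The genes to name were Etv5, Etv1, Etv4, Dusp6, Spry2 and Myc; the 12 risen and 12 fallen genes of largest change among single-gene probe sets that passed and whose groups did not overlap, leaving out predicted genes, olfactory, vomeronasal and small RNA genes and immunoglobulin genes; up to 4 members per list with the smallest p; and the sex-linked genes. The rule skipped 1 gene among the fallen ones, Ighm, which is named through its list. Genes named outside the rule are marked as such. The alternatives were the sample number as a block, a filter that left out the dimmest 40% of probe sets, single-gene probe sets only, quantile, median and cyclic loess normalization, a variance trend with robust settings, array weights, each sample left out in turn, other thresholds, and the mean of a gene's probe sets.

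Sample numbers are shared between the genotypes, but no label says that a number marks a shared animal or day, and the samples were not treated as paired. On simulated data with the spread of these arrays (35556 probe sets), the fit recovered 42% of 100 changes of 0.5 log2 units and 79% of 100 changes of 1, all in the right direction, and 3.97% of its calls were false. Camera called 0 of 20 unchanged and 2 of 2 shifted simulated lists. The probe sets were simulated as independent, with few changed and no structure of the samples besides genotype. The recovered and false shares may therefore differ on the real arrays. The simulation also does not show how often camera with the preset correlation errs on lists of correlated genes.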

Results

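Gene expression was measured on arrays in 6 samples of mouse B cell precursors transformed by BCR-ABL1, the fusion tyrosine kinase of Philadelphia chromosome-positive acute lymphoblastic leukemia. In 3 samples the cells came from wild-type mice and in 3 from mice lacking Etv5, an ETS-family transcription factor of the same subgroup as Etv1 and Etv4. All mice were labelled 129SvEv. The single comparison set by this design is knockout against wild type, and it asks which transcripts differ in the transformed cells when Etv5 is missing. Each array gave 35556 probe-set values on the log2 scale, with array medians between 7.79 and 7.84. Pairs of arrays of the same genotype correlated at r = 0.994 to 0.997 in the wild type and r = 0.995 to 0.996 in the knockout, across probe sets that are not independent replicates. The 9 pairs across genotypes lay between 0.991 and 0.994. The highest of them, wild-type sample 2 with knockout sample 1 (0.9941), exceeded the lowest wild-type pair, samples 2 and 3 (0.9939). The first principal component held 38.2% of the variance and placed the 3 knockout arrays on one side and the 3 wild-type arrays on the other. The second held 24.0% and did not follow genotype: wild-type sample 2 and knockout sample 1 had its highest scores, and wild-type sample 3 and knockout sample 3 its lowest. The median SD between samples of a genotype was 0.087 log2 units in the wild type and 0.098 in the knockout. The labels do not state whether the 3 samples of a genotype came from separate mice or cultures, so the p-values below measure only the spread between these samples, which may be technical.

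Between the samples labelled knockout and wild type, large differences lay in a limited part of the transcriptome. Enpep, which encodes the BP-1 aminopeptidase found on early mouse B lineage cells, rose 16.6-fold, from 8.33 ± 0.043 in the wild type to 12.39 ± 0.0061 in the knockout (log2 signal, SD, n = 3 each). Ighm, the heavy chain constant region of IgM, fell by 3.30 ± 0.12 (SE) on the log2 scale, from 11.82 ± 0.23 to 8.53 ± 0.042. Other B lineage genes moved both ways: Ly6d rose by 1.96 ± 0.19 and Cxcr5, the chemokine receptor of follicular B cells, fell by 2.79 ± 0.15. By limma with Benjamini-Hochberg adjustment at 0.05, 1095 of 35556 probe sets changed, 580 higher and 515 lower in the knockout. Of 19938 genes named by a single-gene probe set, 483 rose and 401 fell. The change reached 1 log2 unit for 125 risen and 79 fallen genes, and 2 log2 units for 23 and 15. In all 1095 changed probe sets the 3 knockout values lay apart from the 3 wild-type values, as they did in 16.5% of all probe sets, where chance gives 10%. Leaving out wild-type sample 1, wild-type sample 2 or knockout sample 3 lowered the count to 565, 620 and 586.

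Among the 12 most risen genes, the largest rises after Enpep were those of Ly6f, a member of the Ly6 surface protein family, which rose by 3.52 ± 0.11 (SE, log2, adjusted p = 9.8e-05), and Cyp4f18, a leukotriene-metabolising cytochrome P450, which rose by 3.29 ± 0.083 (adjusted p = 5.34e-05). Lgals1, encoding the carbohydrate-binding protein galectin-1, rose by 3.10, the aldehyde dehydrogenase gene Aldh1a7 by 3.08 and Crhbp, encoding a binding protein of corticotropin-releasing hormone, 7.97-fold. The T cell receptor gamma variable segment Trgv1 rose by 2.99 from a dim signal of 5.57 ± 0.40. The transcriptional repressor gene Bhlhe41 rose by 2.79, Pla2g7, encoding the enzyme that inactivates platelet-activating factor, by 2.78, and Umod, encoding uromodulin, by 2.78. The calcium-dependent kinase gene Camk4 rose by 2.66 and the transporter gene Slc16a14 5.66-fold. The adjusted p-values of these 12 genes, from limma, lay between 3.49e-06 and 0.00108.

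Among the 12 most fallen genes were Glp1r, Epcam and Stag3. Glp1r, the receptor of glucagon-like peptide-1, had a log2 change of -2.96 ± 0.090 (SE, limma adjusted p = 8.8e-05). Epcam, an epithelial adhesion molecule, changed by -2.93, and the chemokine receptor gene Cxcr5 by -2.79. The receptor tyrosine kinase gene Ret fell from 11.21 ± 0.042 to 8.74 ± 0.17 (SD, n = 3), a log2 change of -2.47, and Pgr, the progesterone receptor gene, fell to 8.64 ± 0.18, a log2 change of -2.36. Stag3, which encodes a meiotic cohesin subunit, changed by -2.93 and Dkkl1, known from developing sperm, by -2.46. The remaining fallen genes were Ccdc38 (-2.78), the sodium-proton exchanger gene Slc9b1 (-2.54), Nav1 (-2.40), the sialic acid hydroxylase gene Cmah (-2.26) and the phosphodiesterase gene Gdpd3 (-2.22). Ccdc38 and Slc9b1 in the knockout (5.90 and 5.76), like Trgv1 in the wild type, lay below the highest mean of a Y-linked gene (6.12 for Kdm5d), so these signals were not shown to be above background and the sizes of the 3 changes are uncertain. Adjusted p-values of these 12 genes, from limma, ran from 8.8e-05 to 0.00166. All 24 of the most changed genes kept their call in every alternative setting tried.

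**Figure D1:**
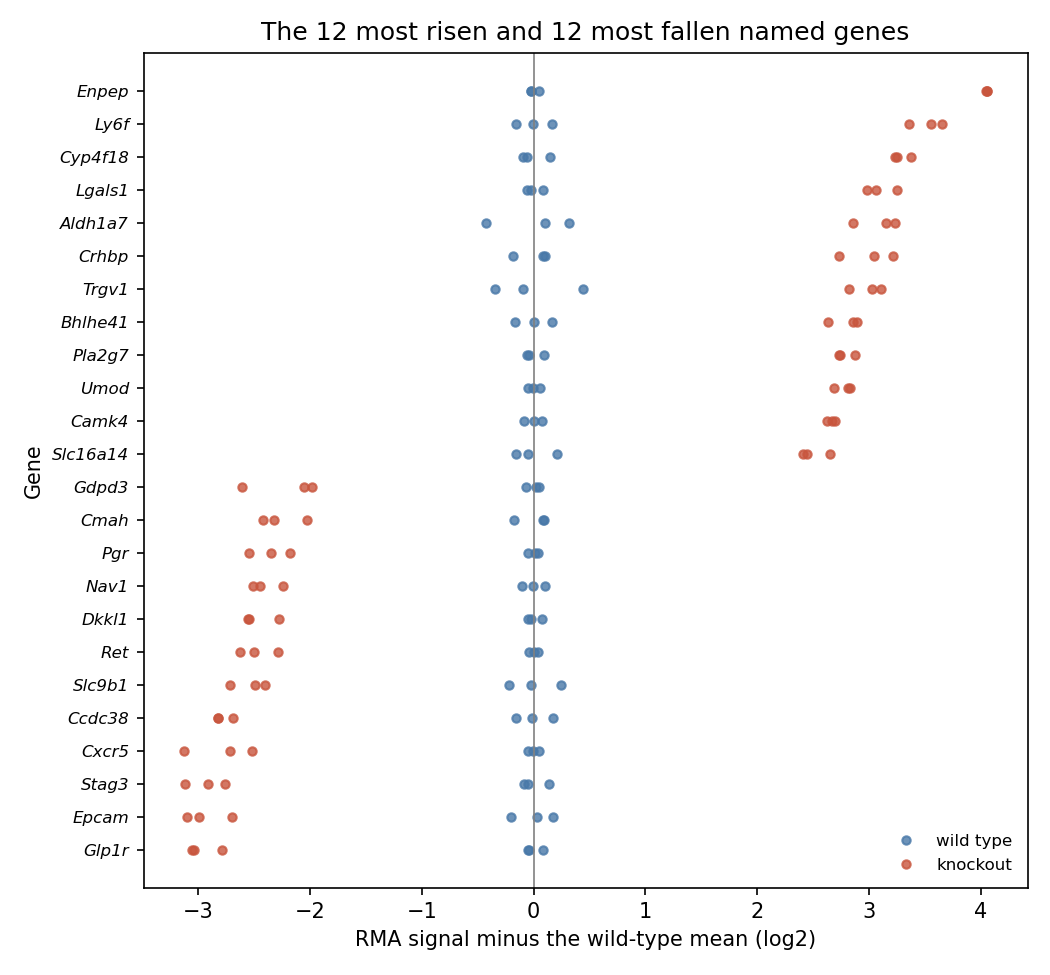
RMA signal of each array minus the wild-type mean of the gene (log2, horizontal axis) for the 12 most risen and 12 most fallen named genes (vertical axis); each point is 1 array, 3 per genotype. Enpep stands farthest from 0 at 4.05, and in each gene the 3 knockout points lie apart from the 3 wild-type points.

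Etv5 itself differed little between the genotypes on these arrays. Etv5 is represented by a pair of probe sets. Probe set 10438626, whose neighbour in number is the Etv5 neighbour Tra2b, gave 9.30, 9.52 and 9.27 in the wild-type samples and 8.97, 8.91 and 8.92 in the knockout samples, a fall of 1.35-fold (log2 change -0.43, 95% interval -0.63 to -0.24, limma adjusted p = 0.0467). Probe set 10363901, numbered between probe sets of Ipmk and Hbs1l, genes of another chromosome, gave 11.48, 11.52 and 11.46 in the wild type and 11.67, 11.88 and 11.73 in the knockout (log2 change 0.28, adjusted p = 0.13); Ipmk, chosen after its value was seen, rose by 0.71 (adjusted p = 0.00181). The direction of the first goes with the labels, but the signal remaining in the knockout was 8.93 ± 0.033 (SD, n = 3). Which exons the knockout allele lacks and where the probes lie are not given in the sources used here. It is therefore not known whether either probe set tests the deletion itself. The fall of the first probe set lost its call in each fit that left out 1 sample (adjusted p 0.0712 to 0.18; 0.011 to 0.18 over all alternatives).

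Among genes that ERK signalling induces or that restrain it, 3 of 30 changed, a larger share than the 884 of all 19938 genes. Egr1, an immediate-early transcription factor, rose by 0.61 ± 0.088 (SE, log2, limma adjusted p = 0.0193), Jun by 0.29 (adjusted p = 0.0457) and Spred1, an inhibitor of RAS-ERK signalling, by 0.27 (adjusted p = 0.0478). Of the 30 measured members of the list of ERK feedback genes and targets, these 3 rose, none fell and 27 did not pass. Adjusted over the list alone, 3 rose and 2 fell. At an unadjusted limma p under 0.05, 6 were higher and 2 lower, beside 3913 of all 35556 probe sets in either direction. The ERK phosphatase gene Dusp6 was bright in both genotypes, at 12.29 ± 0.0082 and 12.39 ± 0.048 (SD, n = 3), with a log2 difference of 0.09 (95% interval -0.03 to 0.22, adjusted p = 0.622). The ERK inhibitor gene Spry2 differed by 0.06 (95% interval -0.11 to 0.23). The Etv5 relatives Etv4 and Etv1 differed by 0.22 and 0.11 (adjusted p = 0.526 and 0.713), and the cytokine gene Lif by -0.53 (adjusted p = 0.131). Among 22 measured pathway components, Rasgrp1, a RAS activator of lymphocytes, rose by 0.55 (adjusted p = 0.00357), the adaptor gene Gab1 rose by 0.41 (adjusted p = 0.0252), none fell and 20 did not pass; adjusted over the list alone, 2 rose. Neither list as a whole passed camera (adjusted p = 0.0811 and 0.0881). With array weights both lists passed (adjusted p = 0.0487 and 0.0414), and the components also passed without wild-type sample 3 (0.0392) or knockout sample 1 (0.0474). With an estimated correlation and all samples, the adjusted p-values were 0.80 and 0.848. Leaving out 1 sample at a time, Jun and Spred1 lost their call in each of the 6 fits (adjusted p 0.0574 to 0.192 and 0.101 to 0.178), Gab1 in 5, all but that without knockout sample 1 (highest adjusted p 0.113), and Egr1 in 3, without wild-type sample 1, wild-type sample 2 or knockout sample 3 (highest 0.0949).

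**Figure D2:**
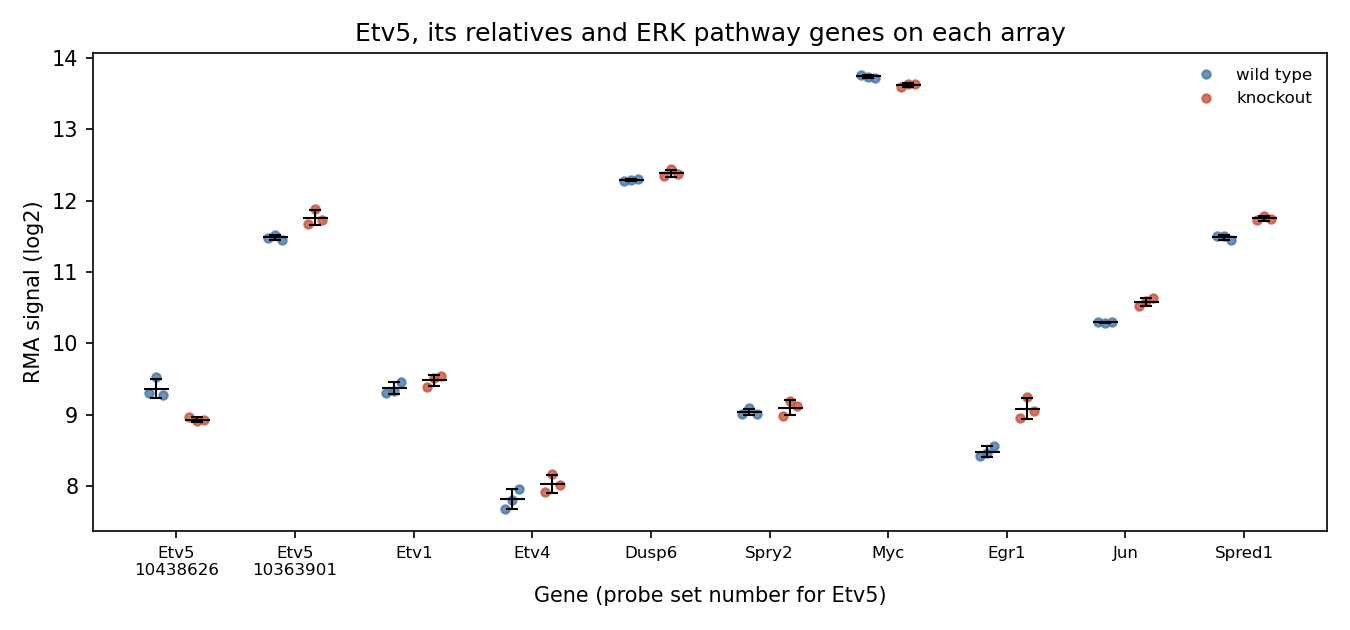
RMA signal (log2, vertical axis) of both Etv5 probe sets, Etv1, Etv4, Dusp6, Spry2, Myc and the 3 ERK-responsive genes that passed the test (horizontal axis); points are arrays, bars mean ± SD of 3 samples. Probe set 10438626 of Etv5 is 0.43 lower in the knockout, whereas Dusp6 differs by 0.09 and Spry2 by 0.06.

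B lineage genes changed in both directions. Of 30 measured B cell precursor genes, 5 rose, 3 fell and 22 did not pass; adjusted over the list alone, 9 rose and 4 fell. The risen ones included Ly6d, Bst1, the surface antigen BP-3 (log2 change 0.81, adjusted p = 0.00107), the transcription factor gene Irf4 (0.52, adjusted p = 0.00689) and Pax5, which maintains B lineage identity (0.43, adjusted p = 0.0127). The 3 that fell were Dntt, Irf8 and Vpreb2 (-0.37, -0.34 and -0.32, limma adjusted p = 0.0132, 0.0315 and 0.045). The pre-B cell receptor surrogate light chain gene Igll1 and the receptor genes Il7r and Cd79a were bright in both genotypes. They differed by -0.04, 0.07 and 0.13, without passing the test. The 3 fallen genes and Igll1, Il7r and Cd79a were named after their values were seen. Of 24 mature B cell genes, 4 rose, 2 fell (Ighm and Cxcr5) and 18 did not pass; adjusted over the list alone, 9 rose and 2 fell. Spib, an ETS factor of B cells, rose by 0.75 (adjusted p = 0.00255) and the Fc receptor-like gene Fcrla rose by 1.23 (adjusted p = 0.00433). Ighm had 2 more probe sets, which were dim and differed by 0.12 and -0.28 (adjusted p = 0.621 and 0.626), so its fall rests on the brightest one. Of 24 genes of pre-B cell receptor signalling, 5 rose, none fell and 19 did not pass (7 rose and 4 fell adjusted over the list alone). They included the kinase genes Blk (1.03, adjusted p = 0.00203) and Syk (0.34, adjusted p = 0.0265) and the adaptor genes Bank1 (0.65, adjusted p = 0.0125) and Pik3ap1 (0.48, adjusted p = 0.0248). Camera, with a preset correlation of 0.01, called all 3 lists up (adjusted p = 0.00896, 0.0227 and 0.0069), although the mean of the mature B cell list was -0.04 beside a median of 0.08. None of the 3 held with an estimated correlation (adjusted p = 0.80 for each). Of the 6 fits that left out 1 sample, Syk lost its call in 6, Pik3ap1 in 5, and Bank1 and Pax5 in 3 each (highest adjusted p 0.118, 0.114, 0.0658 and 0.0751).

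Several STAT5 targets and genes of the p53 list rose in the knockout. The STAT5 targets Cish, a feedback inhibitor of cytokine receptors, Bcl2l1, which encodes the survival protein BCL-XL, and Il2ra rose by 0.80, 0.63 and 0.56 (limma adjusted p = 0.00176, 0.00499 and 0.00914), while Xbp1 fell by 0.54 (adjusted p = 0.0046). Of 20 STAT5 targets, 4 rose, 1 fell and 15 did not pass; adjusted over the list alone, 6 rose and 1 fell. In the list of p53 targets and cell cycle inhibitors, the antiproliferative gene Btg2 rose by 1.29 (adjusted p = 0.00284), the tumour suppressor locus Cdkn2a by 0.67 (adjusted p = 0.00294) and the p53 target Zmat3 by 0.59 (adjusted p = 0.0376). Over all genes tested, these 3 of 25 rose and none fell; adjusted over the list alone, 15 rose and 1 fell. Camera called both lists up, with adjusted p = 0.00468 for STAT5 targets and 5.51e-07 for the p53 list, and both lost the call with an estimated correlation (adjusted p = 0.80 for each). Of 22 apoptosis regulators, Bcl2l1 and Birc3 (0.31, adjusted p = 0.0264) rose, Bok (-0.47, adjusted p = 0.0158) fell and 19 did not pass (4 rose and 3 fell adjusted over the list alone); the list did not pass camera (adjusted p = 0.779). Of the 6 fits that left out 1 sample, Birc3 lost its call in 6, Zmat3 and Bok in 5 each and Il2ra in 2 (highest adjusted p 0.131, 0.156, 0.0832 and 0.0554). None of 35 cell cycle genes passed limma, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05; this gene, Aurka, differed by -0.14 (adjusted p = 0.36), and the median of the list was -0.016.

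Stem and progenitor genes rose in part. Igf2bp3, an RNA-binding protein of fetal progenitors, rose from 7.93 ± 0.13 to 10.43 ± 0.17 (SD, n = 3), a 5.66-fold change (limma adjusted p = 0.000224). The progenitor receptor gene Flt3 rose by 1.27 (adjusted p = 0.00192), Mycn by 0.48 (adjusted p = 0.00897) and Lmo2 by 0.35 (adjusted p = 0.0311). In all, 6 of 20 members rose, none fell and 14 did not pass, with the same counts adjusted over the list alone. The list passed camera (adjusted p = 0.00166) and fry, which tests whether a list moves on balance one way (adjusted p = 0.000312), but not camera with an estimated correlation (adjusted p = 0.318). Leaving out 1 sample, Lmo2 lost its call in 5 of 6 fits and Mycn in 1 (highest adjusted p 0.144 and 0.0519).

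Metabolic and stress lists showed small or mixed changes. Of 29 genes of the ATF4 and unfolded protein responses, 4 fell, 1 rose and 24 did not pass (6 fell and 1 rose adjusted over the list alone). Xbp1, a transcription factor of the unfolded protein response, the serine synthesis gene Phgdh (-0.50, limma adjusted p = 0.00712) and the cystine transporter gene Slc7a11 (-0.56, adjusted p = 0.0174, with a dim signal of 5.95 in the knockout) fell, and Chac1, a glutathione-degrading enzyme induced by ATF4, rose (0.48, adjusted p = 0.0132). No member of 29 ribosome biogenesis genes and MYC targets passed limma, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. Their median was -0.063, Utp20 differed by -0.22 (adjusted p = 0.0841) and Myc by -0.12 (adjusted p = 0.417). Camera called both lists down (adjusted p = 0.00896 for each), and neither held with an estimated correlation (adjusted p = 0.80 for each). Of 26 glycolysis and hypoxia genes, 3 rose and 2 fell (4 and 4 adjusted over the list alone): the mitophagy receptor gene Bnip3 (0.61, adjusted p = 0.00287) and the mTOR inhibitor gene Ddit4 (0.87, adjusted p = 0.00366) rose, whereas the oxygen sensor gene Egln3 (-1.09, adjusted p = 0.00363) and the pyruvate dehydrogenase kinase gene Pdk1 (-0.45, adjusted p = 0.00667) fell. None of 20 cholesterol synthesis genes passed limma, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05; Lss, with the smallest p, differed by -0.19 (adjusted p = 0.255). Of 28 interferon response genes, 3 rose, among them Gbp3 (0.51, adjusted p = 0.0029), and Ifih1 fell (-0.55, adjusted p = 0.0101), with 4 up and 2 down adjusted over the list alone. These last 3 lists did not pass camera (adjusted p = 0.619, 0.345 and 0.619). Leaving out 1 sample, Chac1 and Slc7a11 lost their call in 4 of 6 fits each and Ifih1 in 3 (highest adjusted p 0.0748, 0.0828 and 0.0582).

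Adhesion genes and the markers of other cell types did not shift as groups. Of 25 adhesion and migration genes, 3 rose, 2 fell and 20 did not pass (7 and 5 adjusted over the list alone). The integrin gene Itga5 fell from 9.76 ± 0.061 to 8.19 ± 0.13 (SD, n = 3; log2 change -1.57, limma adjusted p = 0.000381), the tetraspanin gene Cd9 fell (-0.96, adjusted p = 0.0174), and Cd44 (0.91, adjusted p = 0.00108) and Pecam1 (0.46, adjusted p = 0.00811) rose. Of 29 myeloid markers, the integrin gene Itgam rose (0.60, adjusted p = 0.0235) and 28 did not pass. Of 25 T and NK cell markers, Cd2 (1.48, adjusted p = 0.00019) and Zap70 (0.33, adjusted p = 0.047) rose and Cd5 (-0.72, adjusted p = 0.0156) fell. Of 19 erythroid and megakaryocyte markers, the carbonic anhydrase gene Car2 fell (-0.48, adjusted p = 0.00661) and 18 did not pass. Among 26 stromal and endothelial markers, Pecam1 rose and 25 did not pass. None of 13 mast cell and basophil markers passed limma, over all genes or adjusted over the list alone, and 1 had an unadjusted p under 0.05 (Hpgds, 0.44, adjusted p = 0.154). Of 13 plasmacytoid and dendritic cell markers, Flt3 and Spib rose, which also stand in the lists above. Adjusted over the list alone, the myeloid count was 2 and the counts of the other 5 marker lists were as given. Camera adjusted p-values of these 7 lists lay between 0.187 and 0.977. Median and mean differed in sign for adhesion (0.048 and -0.00062), stromal (-0.0015 and 0.0033) and dendritic cell genes (-0.0010 and 0.15), and camera and fry differed in direction for the stromal list. Dendritic cell markers passed camera without wild-type sample 2 (adjusted p = 0.0408), and erythroid markers without knockout sample 1 (adjusted p = 0.0489); with an estimated correlation and all samples, the adjusted p-values were 0.80 and 0.848. Of the 6 fits that left out 1 sample, Zap70 lost its call in 6, Itgam and Cd5 in 4 each, Cd9 in 3 and Pecam1 in 1 (highest adjusted p 0.183, 0.112, 0.0702, 0.0863 and 0.0518). Xist was at 13.6 in both genotypes (log2 difference -0.02), and the Y-linked genes Uty, Kdm5d and Eif2s3y lay at 5.76, 6.12 and 4.77 or below in either group mean, so the sex-linked genes did not separate the genotypes. None of 13 measured replication-dependent histone genes passed limma, and 0 had an unadjusted p under 0.05.

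**Figure D3:**
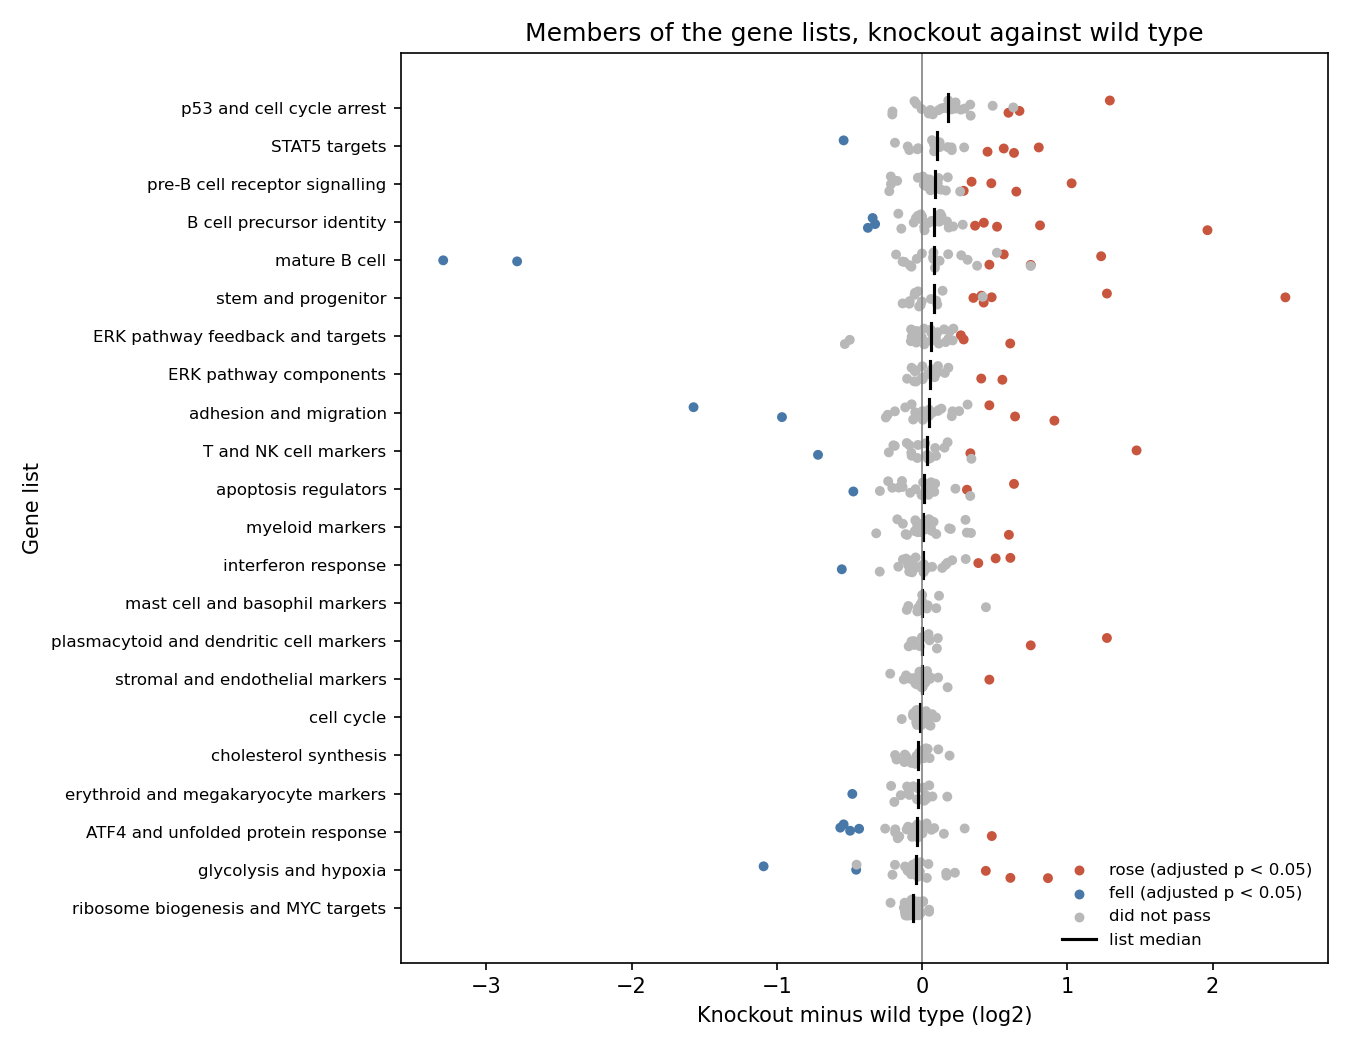
Log2 change, knockout minus wild type (horizontal axis), of every measured member of the 22 tested gene lists (vertical axis); coloured points passed limma at an adjusted p of 0.05, grey points did not, and black bars are list medians. The list medians lie between -0.063 and 0.18, the highest being that of the p53 list.

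Among the 20 measured genes on each side of Etv5 in the order of the reference gene table, 3 of 40 (7.5%) passed limma, against 4.44% of all genes placed in the table, and the median log2 change was -0.03. They were Magef1 and Fetub, which rose by 0.52 and 1.32 (adjusted p = 0.00905 and 0.00951), and the sialyltransferase gene St6gal1, which fell by 0.54 (adjusted p = 0.00973); these were chosen after their values were seen. With 50 genes on each side, 4 of 100 passed.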

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

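The count of 1095 changed probe sets ran from 1048 to 1452 under the filter, annotation, normalization, variance and weight alternatives. The first 2 tested fewer probe sets. With the filter 1294 of 21333 passed, 952 of them also among the 1095. With single-gene probe sets only, 1394 of 21789 passed, 940 of them among the 1095. Under the normalization, variance and weight alternatives, 1020 to 1092 were also among the 1095. Leaving out 1 sample gave 565 to 857, with fewer samples by construction; the lowest counts came without wild-type sample 1 (565), knockout sample 3 (586) and wild-type sample 2 (620). With the sample number as a replicate block, 544 probe sets passed, 533 of them also among the 1095. Deviations from the genotype means correlated at -0.12, 0.016 and 0.26 within equal numbers, and 2 of 6 samples correlated best with their own number. These values give no evidence that the numbers pair the samples, but with 3 samples per genotype they cannot exclude it. Requiring a change of 1 log2 unit left 252, and a count without a model, chosen after seeing the data (groups apart and at least 1 log2 unit), gave 258. The fall of Etv5 on probe set 10438626 kept its direction but missed the threshold with the block (-0.43, adjusted p = 0.144), quantile normalization (-0.44, adjusted p = 0.0815), cyclic loess (-0.44, adjusted p = 0.055) and each sample left out (-0.48 to -0.35, adjusted p 0.0712 to 0.18); over all alternatives its adjusted p ran from 0.011 to 0.18. The rise on probe set 10363901 passed with single-gene probe sets only (0.28, adjusted p = 0.0486) and with the variance trend (0.28, adjusted p = 0.0437), within 0.0437 to 0.362 over all alternatives. Of 22 lists, 8 passed camera, 0 with an estimated correlation (lowest adjusted p = 0.318) and 1, the stem and progenitor list, with fry; the cause was not tested. Of 118 named genes other than Etv5, 73 were called, and 46 of these, all 24 of the most changed among them, kept their call in every alternative; no called gene changed direction, while 4 uncalled ones changed sign somewhere. Of the 27 that lost it somewhere, Jun, Spred1, Syk, Birc3 and Zap70 lost it whichever sample was left out. Pdk1, Phgdh and Car2 lost it in 1 alternative each, which did not leave out a sample. With array weights 10 lists passed, both ERK lists among them. Without detection calls, a limit of detection for dim genes such as Trgv1, Ccdc38 and Slc9b1 is not known here.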

Other observations

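Genes named in this part outside the rule for named genes, and the tests of myeloid cells, of whole chromosomes and of the share of changed genes on chromosome 16 were chosen after the result was seen. Several genes outside the fixed lists moved strongly. The insulin-like growth factor receptor gene Igf1r fell by 1.69 ± 0.054 (SE, log2, limma adjusted p = 9.8e-05), the imprinted receptor gene Igf2r rose by 1.73 (adjusted p = 0.000747) with its antisense transcript Airn (0.85, adjusted p = 0.00244), and the imprinted receptor adaptor gene Grb10 changed by -0.83 (adjusted p = 0.00371). The metal-binding proteins Mt1 and Mt2 changed by -1.38 and -1.66 (adjusted p = 0.000642 and 0.00299). Among signalling genes, the JAK family kinase gene Tyk2 fell by 1.33 (adjusted p = 0.000313), Mtor rose by 1.28 (adjusted p = 0.000427), and Il10ra and the inhibitory receptor gene Siglecg rose by 2.31 and 1.95 (adjusted p = 0.000188 and 0.00019). Jchain, which joins IgM and IgA polymers, fell by 1.67 (adjusted p = 0.00182), in the same direction as Ighm. Whether the arrays counted strand for Igf2r and Airn is not given.

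The 1095 changed probe sets compare with 0 in each of the other splits of the 6 samples 3 against 3. Those splits set samples of both genotypes on each side, so genotype differences widen their spread and hold their counts down. The real split was 1 of 10, too few for a share under 0.05. At an unadjusted p under 0.05, limma gave 3913 probe sets in the real split and 653 to 4294 in the others; the highest set wild-type samples 1 and 2 and knockout sample 1 against the rest, which points to a structure of the samples besides genotype. No label names a batch that follows it.

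Among the risen genes of the knockout were Cybb (log2 change 2.44), Pla2g7, Lgals1 and Itgam, which myeloid cells also express. Myeloid cells in the knockout cultures are argued against as the source of a rise of the size of that of Cybb: the median change of 29 myeloid markers was 0.0073 with a standard error of 0.020, below the bound of 1.22 set from the change of Cybb. Of the 29 markers, 5 were higher and 1 lower at an unadjusted p under 0.05; beside Itgam (0.60, passing), Mrc1, Fcgr3 and Cd68 differed by 0.31, 0.30 and 0.34 without passing. The abundant myeloid genes Lyz2, Tyrobp and Mpo differed by -0.32, 0.02 and -0.02. The bound assumes that myeloid cells would raise the typical marker along with Cybb, which was not tested. A small share of myeloid cells that raises only some markers stays open. A change within the transformed cells also stays open and was not tested.

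Many probe sets differed between genotypes by more than the spread between samples of a genotype. Whole arrays did not separate as clearly. Wild-type sample 2 correlated slightly better with knockout sample 1 (r = 0.9941) than with wild-type sample 3 (r = 0.9939). If the 3 samples of a genotype were drawn from 1 culture, the comparison would be of a pair of transformed populations, and differences between clones could not be told apart from those of Etv5. Immunoglobulin variable-segment probe sets, which separate clones could be expected to differ in, varied within genotypes at the 36.1 percentile of random probe sets of equal signal (25 probe sets, median SD 0.12), which decides nothing, since cultures of many clones also look alike. Gain or loss of whole chromosomes is argued against, since no chromosome's median change exceeded 0.012 in size. An effect of DNA flanking the knocked-out allele on its own chromosome is argued against as the cause of most differences. Of 884 changed genes, 31 lay on chromosome 16, which carries Etv5. There 4.78% of the placed genes changed, against 4.44% of all placed genes. An effect of flanking DNA on genes of other chromosomes was not tested and stays open. For the 3 changed genes among the 40 neighbours of Etv5, flanking DNA stays open too, as 27.7% of all windows of 40 genes held as many.

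Changed genes lay beside each other more often than random placement gives: of genes in reference order, 91 neighbouring pairs had both changed, against a median of 44 in 10000 random placements matched on signal (95% range 32 to 57, permutation p = 1e-04, the smallest these can give). Probes shared between neighbours of like symbol are argued against as the whole cause. When pairs sharing the first 3 letters of their symbols were left out, 77 pairs remained, above the random range of 30 to 53. Symbols are a rough guide, so related neighbours with unlike symbols can remain among the 77. In 80.2% of the pairs, 73 of 91, both genes went the same way, against a range of 37 to 55 in random sign assignments. Transcripts or regulated regions that span neighbours could give this, and other causes were not tested. The count kept the pairs of like symbols, in which shared probes could also give the same direction. Cyp4f18 rose with the olfactory receptor genes Olfr372 and Olfr373 beside it (3.29, 2.15 and 2.02), and Umod with the dim Gp2 (2.78 and 1.03), whereas Pgr and its neighbour Arhgap42 went opposite ways, with changes of -2.36 and 2.38.

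The 3 hypotheses on gene groups below were drawn from strongly changed genes, and camera called none of the lists. The lists were written before their tests, but the values of Dusp6 and Etv4 in the kidney and spermatogonia list had been seen, and the low signals given here were looked at after the tests. Germ cell and meiosis genes were tested for a fall with Stag3, Psma8 and Dkkl1: of 47, 0 fell and 3 (Prm1, Syce2 and Uchl1) rose, 9 had an unadjusted p under 0.05 (5 up, 4 down), and camera pointed down (median -0.015, standard error 0.016, adjusted p = 0.851). In the wild type 43 of the 47 lay below the median probe set (7.81) and 14 below the highest Y-linked mean. Most may therefore have had little signal to lose, and for them nothing is decided. The members above the median were all higher in the knockout, by 0.30 (Syce2) to 0.90 (Prm1). Genes listed as linked to Etv5 in kidney and spermatogonia were tested for a fall with Ret. Of 15, 0 passed limma and 1 had an unadjusted p under 0.05 (down). Camera pointed up (median -0.0017, standard error 0.032, adjusted p = 0.851). In the wild type 8 of the 15 lay below the median probe set. The members above it differed by -0.18 (Gfra1) to 0.22 (Etv4). For these members, that argues against a fall near the size of that of Ret (-2.47). A small fall, or a fall of the dimmer members, stays open. Etv4, Dusp6 and Spred2, all above the median probe set, also stand in the ERK feedback list. Whether each member depends on Etv5 is not given in the sources used here. Genes of fetal and innate-like B lymphopoiesis were tested for a rise with Igf2bp3, Bhlhe41 and Siglecg: of 16, Bhlhe40 rose (0.75) and Ctla4 fell (-1.45), 7 had an unadjusted p under 0.05 (4 up, 3 down), and camera pointed up (median -0.0058, standard error 0.040, adjusted p = 0.851); a shift of the list near the size of the rises of those genes is argued against, and a small one stays open.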
